A study of Arabidopsis thaliana with 11 samples.

How the data were processed

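Small RNA was sequenced from the youngest leaves of Arabidopsis plants grown for 4 weeks on soil, 12 plants to a box, at 22 °C, 75% relative humidity and 8 h of light at 120 µmol per m² and s. There were 11 libraries of 4 genotypes: 3 of wild type, 3 of pad2-1, 2 of vtc2-1 and 3 of the nahG transgenic line. The vtc2-1 libraries are called vtc2-1 1 and vtc2-1 2 here by their replicate labels, while their titles number them 2 and 3. The labels call them repeats and do not say whether they came from separate batches of plants, so p values measure the spread between these libraries. The libraries were made with a ScriptMiner kit modified to carry high-definition (HD) adapters, whose ends are random ligation-tag bases, and TruSeq index primers. Per the labels the values are counts, the raw number of reads of each distinct read sequence in a library, with no normalization. The adapter trimmer, aligner and filters are not given in the sources used here. The labels name TAIR10 as genome build, but the files hold no coordinates, so all coordinates below are exact matches to the RefSeq assembly of the TAIR10.1 build and its annotation.

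The first 4 and last 4 bases of each read were removed as ligation tags. Inserts of 18 to 31 nt were matched to both strands of the nuclear and organelle genomes without mismatches. A read with several matches was divided evenly among them for the class shares, which used inserts of 18 to 26 nt. The RefSeq annotation used here has no transposable element class, so its pseudogene class stands in for those loci. It also lacks the 25S rRNA, so the 4300 nt after each nuclear 5.8S gene were counted as rRNA. Reads that matched no position were counted as adapter-derived when they held the end of the Illumina 5′ adapter, and as CCA-ended when their last 3 bases were CCA.

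The annotation holds 428 mature miRNAs in 326 MIR genes, which are 350 distinct sequences. Arms with the same sequence were 1 feature, and reads equal to the whole mature sequence were counted. Of these sequences 286 were detected and 257 were taken as guide strands, from a list written beforehand or else as the more abundant arm. Small RNA at other loci was counted as reads of 20 to 24 nt with 1 genomic match whose midpoint lay in an annotated gene, pseudogene or noncoding RNA gene, without rRNA, tRNA, organelle and MIR genes.

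Counts were tested in R 4.3.3 with edgeR 4.0.16, by quasi-likelihood tests with TMM normalization and the default low-count filter, on all 11 libraries with genotype as the only term. This left 167 mature miRNAs and 8803 loci. P values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. CPM were scaled by TMM and taken over mature miRNA reads for miRNAs and over counted locus reads for loci. The SE of a log2 change was taken as its size over the square root of the quasi-likelihood F. Each mutant was compared with wild type, and the mutants with each other for miRNAs. Where a genotype had 0 reads at a locus, the fold is a lower bound against a floor of 3 reads over the group. Where it had 1 to 3 reads, the ratio of counts per counted read is given with its exact 95% interval. Intervals and floors cover counting error only, since reads of a PCR library are not independent molecules.

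The 14 miRNA lists were fixed by family: copper, sulfate, phosphate, silencing machinery, tasiRNA triggers, auxin, phase change, leaf development, scarecrow-like, NF-YA, defence, MYB, deeply conserved and Brassicaceae-restricted. Lists with at least 3 measured guide strands were tested by camera in limma 3.58.1, 2-sided with a preset correlation of 0.01, in 36 tests adjusted together. Shares of read lengths and of annotation classes were compared by 2-sided exact permutation tests, whose smallest possible p is 0.1 with 3 against 3 or 2 against 3 libraries, so that none can pass 0.05. Those p values were adjusted within 18 length tests and within 33 class tests.

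These choices, the main alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each mutant against wild type, up to 12 higher and 12 lower miRNAs with the largest change among those past the threshold with a mean of at least 10 CPM in either genotype. It added the guide strands of miR162, miR168, miR395, miR397, miR398, miR399, miR403, miR408 and miR857, and the 5 most abundant miRNAs. For loci it took up to 5 higher and 5 lower with at least 1 CPM, the TAS genes, GSH1 and VTC2. Other miRNAs and loci named in the text were chosen after their values were seen.

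Some choices were made after the data were seen. They are the rRNA window, the 18 to 26 nt range of the class shares, the length shares of genome-matched reads, the grouping of libraries by ligation tags, and the fits with matched ligation tags, with a ligation-tag score or with distinct ligation tags counted. The rule by which a change of sign of a share counts as a reversal was also set after such changes were seen. The ligation-tag composition was the base percentages of the 3′ tags around the 5 most abundant miRNAs, and libraries were grouped by complete linkage at a mean distance of 4 percentage points. The score is the first principal component of that composition. Distinct ligation tags are limited to the combinations of 4 bases at each end, so their counts can level off for abundant miRNAs.

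Alternatives were DESeq2 1.42.0 (its size factors, or its Wald test), the library size of all genome-matched reads, no low-count filter, isomiRs within 2 nt of either end, reads per MIR gene, matches weighted by their number, 21 nt or 24 nt reads alone, only the 2 genotypes compared, replicate blocks and each library left out in turn. List tests were repeated with an estimated correlation and with fry. Reads were counted with Python 3.11.15, NumPy 2.4.6 and Numba 0.67.0, and plots were drawn with Matplotlib 3.10.9. The fits were tested on simulated data: with changes of log2 2 the tests recovered 90, 65 and 80% of changed miRNAs in pad2-1, vtc2-1 and nahG, and 75, 67 and 75% of changed loci. With changes of log2 1 they recovered 35, 25 and 50% of miRNAs and 32, 17 and 30% of loci. No library duplicated another, and libraries of the same number showed no shared pattern (r of −0.41 to 0.32 over 15 pairs), so the replicate numbers were not taken to pair the libraries.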

Results

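The 11 libraries held 10901697 to 20686511 reads each. Between 79.9 and 90.1% of the 18 to 31 nt inserts matched the genome, except in nahG 3 with 66.6% (95% Wilson interval 66.6 to 66.6%). Reads equal to a mature miRNA numbered 499984 to 1864083 per library, fewest in nahG 3. In all libraries 49.9 to 62.4% of matched 21 nt reads began with U and 43.1 to 55.4% of matched 24 nt reads began with A, the first bases known for miRNAs and for heterochromatic siRNAs.

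The libraries fell into groups by the bases of their 3′ ligation tags. Wild type 1 and 2 shared 1 composition with pad2-1 2 and 3. Wild type 3 and pad2-1 1 each stood alone. The vtc2-1 and nahG libraries shared a composition that no wild-type library had. Distances within these groups were at most 3.69 percentage points, and those between them 9.01 to 17.5 points. On the ligation-tag score wild type 3 was at 31.7, near vtc2-1 and nahG (35.1 to 39.7). Wild type 1 and 2 were at −36.9 and −50.4. Fits with this score as covariate therefore compare vtc2-1 and nahG mainly with wild type 3. On the first principal component of miRNA abundance, with 53.7% of the variance, wild type 3 scored 2.92, beside vtc2-1 and nahG (0.90 to 12.7), while wild type 1 and 2 scored −5.42 and −7.05. Genotype and ligation-tag group cannot be told apart for vtc2-1 or nahG against wild type or pad2-1, whereas pad2-1 has 2 libraries that match 2 of wild type.

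**Figure D1:**
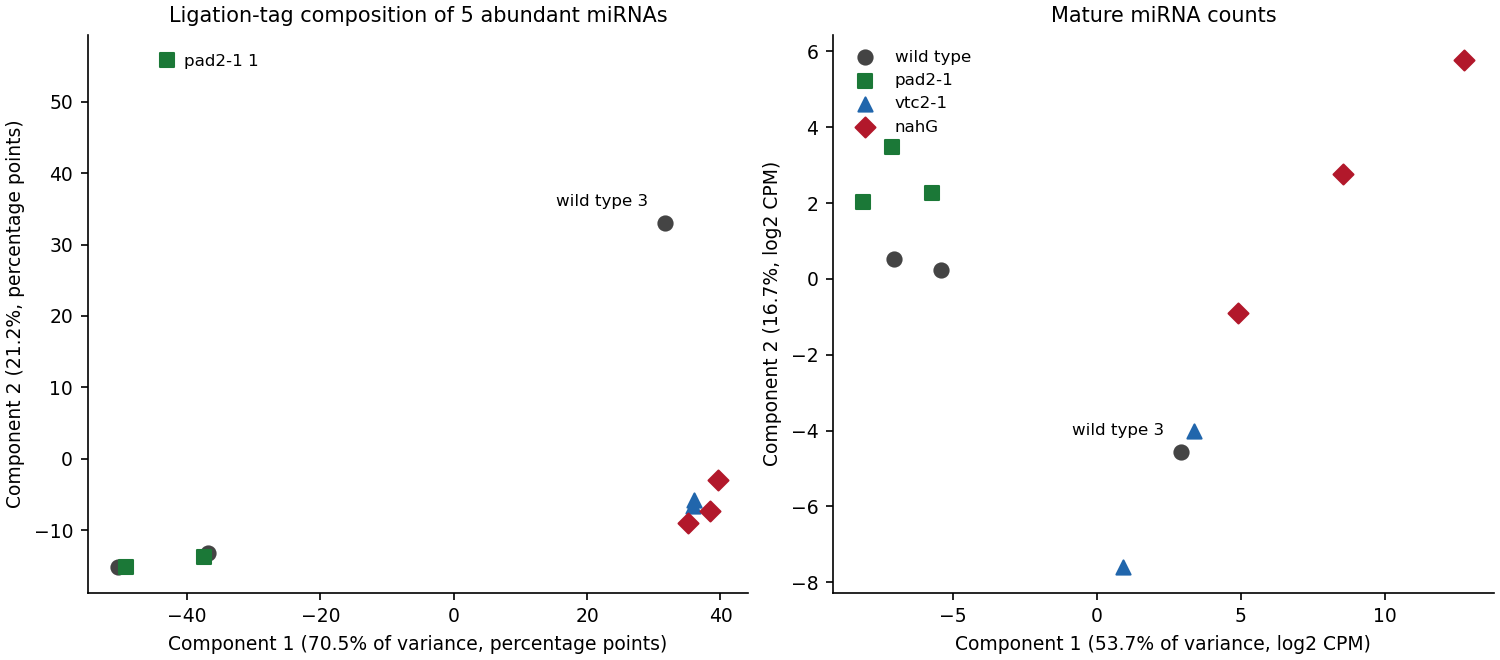
Libraries by the composition of their 3′ ligation tags (left, first 2 principal components) and by the abundance of mature miRNAs (right, first 2 principal components), with 1 point per library and a marker for each genotype. Wild type 3 lies at 2.92 on the first miRNA component, on the side of the vtc2-1 and nahG libraries, while wild type 1 and 2 lie at −5.42 and −7.05.

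The make-up of the small RNA pool was examined in each mutant. The share of rRNA fragments was 40.3% ± 3.06 (SD, n = 3) in wild type, 40.7% ± 2.18 (n = 3) in pad2-1, 49.2% ± 2.01 (n = 2) in vtc2-1 and 53.0% ± 5.88 (n = 3) in nahG. MIR genes gave 16.4% ± 1.76, 17.7% ± 1.55, 12.8% ± 1.06 and 11.2% ± 2.08 in the same order. Over reads with 1 match the difference of the MIR share from wild type was 0.298 points in vtc2-1 and −2.77 in nahG, against −3.60 and −5.16 over all matched reads. That of the rRNA share was 0.668 and 0.945 points, against 8.92 and 12.7. All 3 nahG libraries lay above every wild-type library in rRNA and below every one in MIR reads. The 24 nt class, mostly heterochromatic siRNAs, made up 14.3% ± 1.92 of reads in wild type, 15.1% ± 0.522 in pad2-1, 12.97% ± 0.327 in vtc2-1 and 11.9% ± 0.796 in nahG. Over genome-matched reads its difference from wild type was 2.33 points in pad2-1, −0.599 in vtc2-1 and −1.98 in nahG, against 0.878, −1.30 and −2.34 over all reads. TAS genes, whose transcripts are processed into trans-acting siRNAs, gave 2.00% ± 0.303 of reads in wild type, 2.59% ± 0.168 in pad2-1, above every wild-type library in 3 of 3, 1.61% ± 0.0599 in vtc2-1, outside the wild-type range in 1 of 2, and 1.25% ± 0.398 in nahG, outside it in 2 of 3. The exact permutation tests, whose smallest possible p is 0.1, could not pass for any share, and the lowest adjusted p was 0.3 for classes and 0.969 for lengths.

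The pad2-1 mutation lies in GSH1, which encodes glutamate-cysteine ligase of glutathione synthesis, and per the labels leaves 20 to 25% of wild-type glutathione. The question was which miRNAs respond to low glutathione. Of the copper-responsive miRNAs, miR398a-3p, which directs cleavage of copper/zinc superoxide dismutase transcripts, was at 62.96 ± 8.48 CPM (SD, n = 3) in pad2-1 and 126 ± 23.1 in wild type, a log2 change of −1.001 ± 0.33 (SE; adjusted p = 0.267). The log2 change of miR408-3p, which targets plantacyanin and laccases, was −0.64 ± 0.29 (adjusted p = 0.267), and both were below every wild-type library in 3 of 3. The far more abundant miR398b-3p/c-3p stood at 11982 ± 619 and 13161 ± 1803 CPM. Among phosphate-responsive miRNAs, miR399a, which targets the ubiquitin conjugase PHO2, was at 8.18 ± 0.614 and 4.20 ± 1.06 CPM (log2 change 0.90 ± 0.37, adjusted p = 0.267). None of these passed the test.

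With edgeR, 0 of 167 mature miRNAs passed between pad2-1 and wild type, 30 had an unadjusted p under 0.05, and the Wald test of DESeq2 also called 0. The sulfate-responsive miR395a/d/e (0.05 ± 0.38) and miR395b/c/f (−0.34 ± 0.35), the laccase regulators miR397a (−0.36 ± 0.31) and miR397b (−0.10 ± 0.41), and the regulators of the silencing machinery miR162a-3p/b-3p (−0.29 ± 0.25), miR168a-5p/b-5p (−0.11 ± 0.28) and miR403-3p (0.08 ± 0.26) were within 1 log2 unit of wild type. The log2 changes of miR399b/c-3p and miR399f were 0.35 ± 0.29 and 0.82 ± 0.41. The 5 most abundant miRNAs were miR158a-3p (0.60 ± 0.24), miR167a-5p/b (0.25 ± 0.28), miR159a (−0.35 ± 0.27), the miR166a-3p sequence (−0.51 ± 0.32) and miR396b-5p (−0.86 ± 0.37). Over all alternatives, only the fit without a low-count filter made calls, 9 in number. Counts for miR399d (15 reads in all libraries), miR399e (0) and miR857 (41) were too low to test.

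The lists gave no call in any mutant: 0 of 36 camera tests passed, 7 had an unadjusted p under 0.05, and camera with an estimated correlation and fry also called 0. In pad2-1 the 5 measured copper guides had a median log2 change of −0.36 (adjusted p = 0.0925). Scaling by all genome-matched reads moved the median miRNA by 0.47 in pad2-1 and −0.58 in vtc2-1, and in pad2-1 it turned miR397b and miR398b-3p/c-3p positive, as well as miR159a, miR162a-3p/b-3p and miR168a-5p/b-5p. Adjusted over the list alone, 1 copper member was lower. The 4 NF-YA-directed miR169 guides had a median of 0.78 (adjusted p = 0.0777), and 0 passed over all miRNAs or adjusted over the list alone. Medians of the other pad2-1 lists, again with 0 members past either threshold, were −0.14 for sulfate (2 measured, not tested), 0.58 for phosphate, −0.11 for silencing machinery, 0.28 for tasiRNA triggers (2 measured, not tested), −0.61 for auxin, 0.44 for phase change, −0.35 for leaf development, 0.56 for scarecrow-like, 0.34 for defence, −0.01 for MYB, 0.02 for deeply conserved and 0.36 for Brassicaceae-restricted miRNAs. The MYB median differed in sign from its mean of 0.10. List calls appeared when 1 library was left out, 3 without wild type 3 and 1 without pad2-1 1.

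The vtc2-1 mutation lies in VTC2, a GDP-L-galactose phosphorylase of ascorbate synthesis, and per the labels leaves 25 to 30% of wild-type ascorbate. The question was which miRNAs respond to low ascorbate. In vtc2-1 4 miRNAs rose and 0 fell. They were miR167d, of the family that restrains the auxin response factors ARF6 and ARF8 (104721 ± 26571 CPM, SD, n = 2, against 33122 ± 20999, n = 3), and miR162a-3p/b-3p, which targets DICER-LIKE 1 (14705 ± 876 against 5679 ± 1644 CPM). The other 2 were the partner strands miR159b-5p (318 ± 44.2 against 113 ± 26.5 CPM) and miR166a-5p/b-5p (5733 ± 694 against 2461 ± 772 CPM). The sulfate-responsive miR395a/d/e was at 35.2 ± 8.44 against 97.1 ± 59.7 CPM but did not pass (log2 change −1.46 ± 0.47, adjusted p = 0.159).

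By the edgeR test the log2 changes were 1.66 ± 0.39 for miR167d (SE; adjusted p = 0.0413), 1.49 ± 0.31 for miR159b-5p (0.0201), 1.37 ± 0.28 for miR162a-3p/b-3p (0.0201) and 1.22 ± 0.30 for miR166a-5p/b-5p (0.0413), each above every wild-type library in 2 of 2. Of the other named miRNAs, miR168a-5p/b-5p (0.24 ± 0.31), miR395b/c/f (−0.26 ± 0.40), miR397a (−0.83 ± 0.39), miR397b (−0.15 ± 0.48), miR398a-3p (−0.16 ± 0.37), miR398b-3p/c-3p (−0.25 ± 0.28), miR399a (0.45 ± 0.50), miR399b/c-3p (−0.33 ± 0.32), miR399f (1.38 ± 0.48), miR403-3p (0.07 ± 0.29) and miR408-3p (−0.10 ± 0.32) did not pass. Nor did the abundant miR158a-3p (−0.25 ± 0.27), miR159a (0.42 ± 0.30), miR396b-5p (−0.00 ± 0.41), miR167a-5p/b (−0.47 ± 0.32) and the miR166a-3p sequence (0.66 ± 0.36). Each of the 4 kept its sign in 15 of 15 alternatives. The calls ended without either vtc2-1 library, in fits that leave 1 and take the spread from the other genotypes. They also ended with only the 2 genotypes compared, with distinct ligation tags counted and with replicate blocks numbered as in the titles. All 4 calls ended without wild type 1 or wild type 2, and with the ligation-tag score as covariate, while 28 miRNAs passed without wild type 3. With that score the median of the 4 log2 changes went from 1.43 to 0.88 and the median SE from 0.30 to 0.33. Scaling by all genome-matched reads also ended the 4 calls and turned miR159a, miR168a-5p/b-5p, miR399a and miR403-3p negative. The omission of wild type 3 brought miR395a/d/e (−1.74), miR167a-5p/b (−0.74), miR396b-5p (0.69), miR159a (0.71) and the miR166a-3p sequence (1.17) past the threshold.

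In the lists for vtc2-1, 1 of 5 auxin guides (miR167d) and 1 of 3 silencing-machinery guides (miR162a-3p/b-3p) rose, with medians of 1.38 (adjusted p = 0.236) and 0.24 (0.253), and 2 and 1 were higher adjusted over the list alone. Of the 46 deeply conserved guides 2 rose (median 0.03), and 2 were higher adjusted over the list alone. In the remaining lists 0 members passed over all miRNAs. Adjusted over the list alone, 1 was higher in each of phosphate (median 0.06), leaf development (0.24), defence (0.20) and MYB (0.33), and 1 was lower in sulfate (−0.86). Medians of lists with 0 members past either threshold were −0.16 for copper, −0.45 for tasiRNA triggers, 0.04 for phase change, −0.83 for scarecrow-like, −0.18 for NF-YA and −0.16 for Brassicaceae-restricted miRNAs. The phase-change median differed in sign from its mean of −0.22 and its camera direction.

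The nahG line expresses a bacterial salicylate hydroxylase and per the labels holds 30 to 40% of wild-type salicylate. The question was which miRNAs respond to low salicylate. Both arms of MIR391, a precursor related to MIR390, fell: miR391-3p from 1169 ± 164 to 45.96 ± 18.9 CPM (SD, n = 3 and 3) and miR391-5p from 1302 ± 150 to 101 ± 27.6 CPM. Both miR395 sequences, which target ATP sulfurylases and a sulfate transporter, fell as well, miR395a/d/e from 97.1 ± 59.7 to 10.7 ± 2.82 CPM. Also lower were miR163, which targets methyltransferases of secondary metabolism (1331 ± 564 to 246 ± 51.3 CPM), miR172a/b-3p, which targets AP2-like flowering repressors (4488 ± 2266 to 1375 ± 508 CPM, outside the wild-type range in 2 of 3), and miR393b-3p, a passenger strand with a role in antibacterial defence (3152 ± 324 to 1427 ± 299 CPM). In the other direction miR161.1, which targets pentatricopeptide repeat genes, rose from 39985 ± 18986 to 150487 ± 22426 CPM, and miR162a-3p/b-3p from 5679 ± 1644 to 16337 ± 2512 CPM.

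With edgeR 13 miRNAs rose and 13 fell in nahG, of 167 tested, and 57 had an unadjusted p under 0.05. The log2 change of miR391-3p (ACGGTATCTCTCCTACGTAGC, chromosome 5, 24293211 to 24293231) was −4.69 ± 0.43 (SE; adjusted p = 2.08e-06), and that of miR391-5p (TTCGCAGGAGAGATAGCGCCA, 24293160 to 24293180) was −3.70 ± 0.31 (1.25e-06). For miR161.1 (chromosome 1, 17825731 to 17825751) it was 1.91 ± 0.31 (0.00104), and for miR395a/d/e −3.13 ± 0.47 (5.53e-04). The changes of miR163 and miR162a-3p/b-3p were −2.43 ± 0.41 and 1.52 ± 0.26, each with an adjusted p of 0.00104. The rest of the named lower miRNAs were miR164c-3p (−2.78), miR830-5p (−2.08), miR2112-3p (−1.97), miR172a/b-3p (−1.71), miR395b/c/f (−1.39), miR5996 (−1.31), miR393b-3p (−1.14) and miR3932b-5p (−0.98). The rest of the named higher miRNAs were miR390b-3p (2.33), miR170-5p/miR171a-5p (1.75), miR169b-3p (1.70), miR160a-5p/b/c-5p (1.64), miR159c (1.48), miR165a-5p (1.36), miR165a-3p/b (1.18), miR167d (1.17), miR823 (1.02), miR159b-5p (0.96) and miR159a (0.86), each above every wild-type library in 3 of 3. Named miRNAs that did not pass were miR168a-5p/b-5p (0.31), miR397a (0.62), miR397b (−0.29), miR398a-3p (−0.15), miR398b-3p/c-3p (0.28), miR399a (−0.16), miR399b/c-3p (−0.15), miR399f (0.96), miR403-3p (−0.23), miR408-3p (0.46), miR158a-3p (−0.20), miR167a-5p/b (−0.60), miR396b-5p (0.05) and the miR166a-3p sequence (0.97, adjusted p = 0.0545).

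Of the 26 calls in nahG, 7 held without each single library: miR161.1, miR162a-3p/b-3p, miR163, miR391-3p, miR391-5p, miR395a/d/e and miR830-5p. The count was 11 without wild type 1, 13 without wild type 2, 64 without wild type 3, 8 without nahG 2 and 12 without nahG 3. With distinct ligation tags counted 5 miRNAs were higher and 18 lower, with 18 of the 26 calls among them. Distinct tags ran from 25.2% of mature miRNA reads in wild type 3 to 36.4% in nahG 3. Since their number is also limited, this fit is not a plain check for PCR copies. With the ligation-tag score as covariate 5 calls remained, namely miR161.1, miR164c-3p, miR391-3p, miR391-5p and miR395a/d/e. Over the 21 that ended, all with the same sign, the median size of the log2 change went from 1.39 to 0.95 and the median SE from 0.38 to 0.40. Among them was miR393b-3p (−1.14 ± 0.29 to −1.10 ± 0.38, adjusted p = 0.144). Scaling by all genome-matched reads moved the median miRNA by −0.95 and gave 2 higher and 53 lower miRNAs, the higher ones being miR161.1 and miR160a-5p/b/c-5p.

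**Figure D2:**
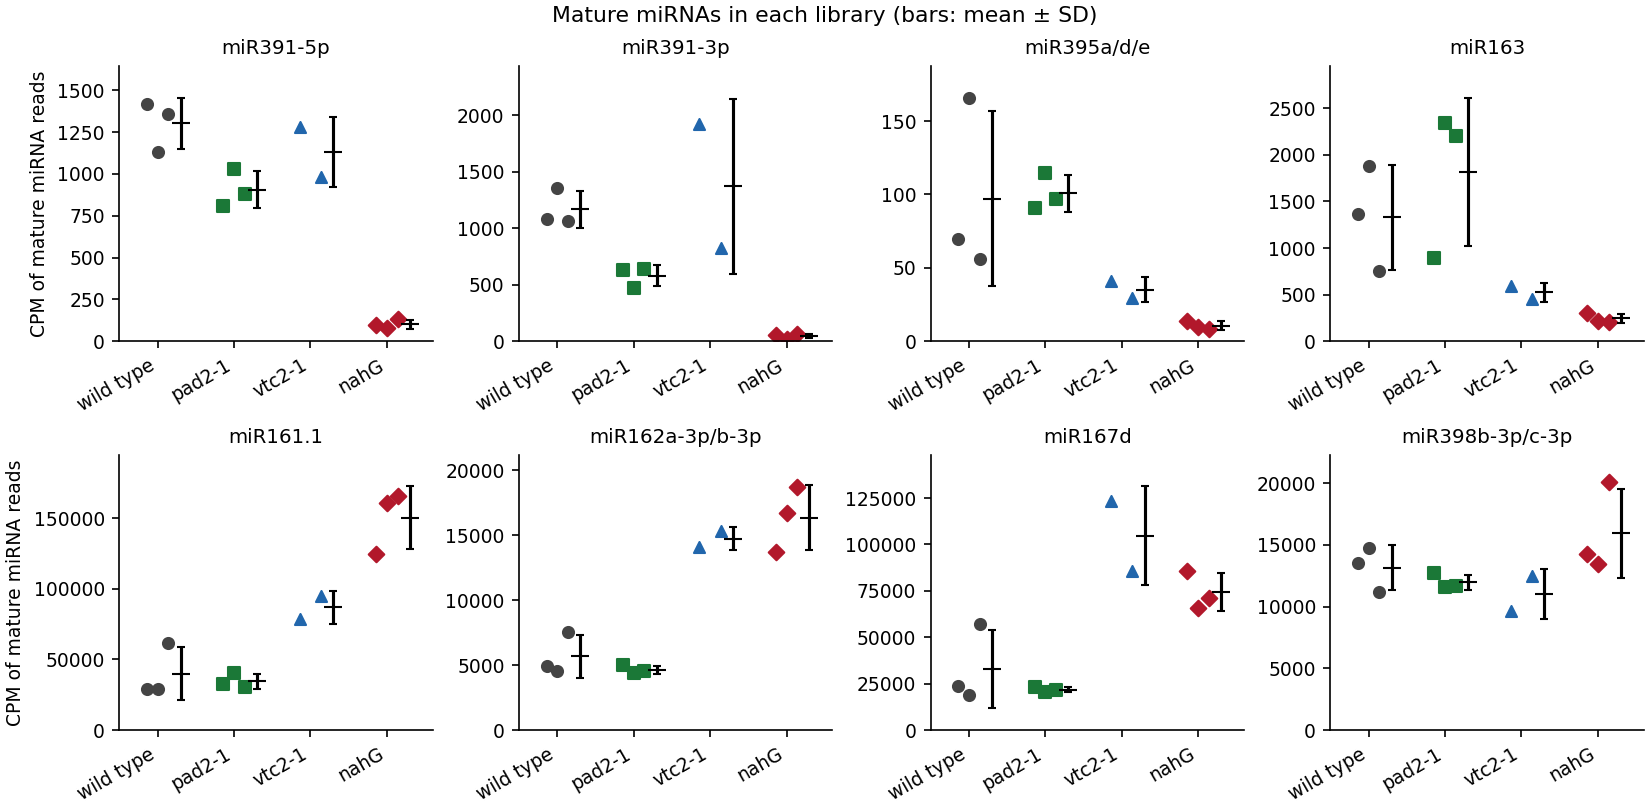
Abundance of 8 mature miRNAs in each library, in CPM of mature miRNA reads on linear axes from 0, with 1 point per library and the mean ± SD of each genotype. In nahG both arms of MIR391 lie below every other library, and miR161.1 has a mean of 150487 CPM against 39985 in wild type.

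In the lists for nahG, both measured sulfate guides fell (median −2.26, 2 lower adjusted over the list alone, not tested as a list). Of 11 leaf-development guides 3 rose (miR159a, miR159c and miR165a-3p/b), with a median of 0.75 (adjusted p = 0.0777) and 5 higher adjusted over the list alone. The MYB list, which shares its miR159 members, had 2 of 5 higher, a median of 0.86 (adjusted p = 0.0777) and 3 higher adjusted over the list alone. Of 5 auxin guides 2 rose (median 0.46, 2 adjusted over the list alone), of 3 silencing-machinery guides 1 (0.31, 1) and of 9 defence guides 1 (0.23, 1). Among 7 phase-change guides 1 fell (median −0.05, 2 lower adjusted over the list alone). Deeply conserved miRNAs had 6 higher and 3 lower of 46 (median 0.20, 7 and 3 adjusted over the list alone), and Brassicaceae-restricted ones 2 higher and 2 lower of 42 (−0.18, 2 and 2). No member passed over all miRNAs in copper (median 0.28), phosphate (−0.15), tasiRNA triggers (−0.20, 1 lower adjusted over the list alone), scarecrow-like (−0.19) and NF-YA (0.50), and the camera direction of scarecrow-like was up. With the library size of all genome-matched reads miR168a-5p/b-5p, miR396b-5p, miR397a, miR398b-3p/c-3p and miR408-3p turned negative.

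The mutants were also compared with each other, and the miRNAs named here were chosen after their values were seen. Both arms of MIR391 and miR393b-3p were higher in vtc2-1 than in nahG, by log2 4.92 ± 0.45 (SE; adjusted p = 2.11e-06) for miR391-3p, 3.50 ± 0.32 (2.11e-06) for miR391-5p and 1.69 ± 0.32 (0.00511) for miR393b-3p. These were the only calls of edgeR between vtc2-1 and nahG (27 at unadjusted p under 0.05), whose libraries share 1 ligation-tag composition. No pad2-1 library has that composition, so in the comparisons of pad2-1 with vtc2-1 and nahG genotype and ligation-tag group cannot be told apart. Between pad2-1 and vtc2-1, 15 miRNAs were higher and 19 lower in pad2-1. Examples are miR172a/b-3p at 9572 ± 1217 against 1958 ± 86.8 CPM (log2 2.29 ± 0.46) and miR160a-5p/b/c-5p, which targets ARF10, ARF16 and ARF17, at 2807 ± 511 against 17798 ± 1817 CPM (−2.66 ± 0.53). Between pad2-1 and nahG, 37 were higher and 31 lower in pad2-1, among them miR391-3p (3.68 ± 0.41), miR395a/d/e (3.18 ± 0.47) and miR161.1 (−2.12 ± 0.32). Without vtc2-1 1, which leaves 1 vtc2-1 library, the difference of miR393b-3p between vtc2-1 and nahG was 1.37. The calls between pad2-1 and vtc2-1 were 3 higher and 8 lower without pad2-1 2, and 1 and 8 without pad2-1 3. The 15 higher calls, miR172a/b-3p among them, ended without either of the 2 vtc2-1 libraries, which leaves 1. Some of the lower calls remained in those fits, and why the higher ones ended was not tested. For miR172a/b-3p these 2 libraries lay close together (1958 ± 86.8 CPM). The count between pad2-1 and nahG was 44 without pad2-1 2, 38 without pad2-1 3, 37 without nahG 2 and 38 without nahG 3. Between vtc2-1 and nahG it was 5 without vtc2-1 2, and 2 without vtc2-1 1.

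Small RNA at other loci differed sharply between pad2-1 and wild type at a set of protein-coding genes and noncoding RNAs, most of them with mainly 24 nt reads. In pad2-1, reads over AT1G47389 (chromosome 1, 17378580 to 17379391) were at least 78.5-fold higher and those over XTH15, a xyloglucan endotransglucosylase of the cell wall (chromosome 4, 8137020 to 8138392), at least 28.6-fold higher, with 0 reads in wild type. AT1G70080 had 709 reads against 3, a ratio of 213 (95% interval 72.7 to 1036). In the other direction AT1G14780 (chromosome 1, 5090809 to 5094152) fell by 7.22 ± 0.74 on the log2 scale (277 ± 176 to 1.84 ± 3.18 CPM, SD, n = 3 and 3), the defensin-like LCR26 by 5.64 ± 0.53 and AT2G37130 by 5.31 ± 0.48. The pad2-1 reads of AT1G14780 came from pad2-1 3 alone (5.52 CPM). Its log2 change ran from −10.5 to −6.34 over the alternatives, past the threshold in 15 of 15.

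By the edgeR test 27 loci rose and 54 fell in pad2-1, of 8803 tested. The other named loci were AT2G05675 (at least 16.5-fold higher), AT4G05605 (ratio 111, interval 30.4 to 921), and, lower, AT1G64035 (ratio 84.3, 28.5 to 412) and the beta-glucosidase gene BGLU45 (38.8, 10.3 to 327). Adjusted p values of the named loci ran from 4.91e-08 to 0.00122, with 3 of 3 pad2-1 libraries outside the wild-type range. At least 50% of reads were 24 nt long at 81.5% of the higher and 83.3% of the lower loci, against 49.3% of tested loci (adjusted p = 0.00236 and 1.47e-06, Fisher's exact test). Here and below this test counts loci called from the same libraries as independent, so its p values do not measure the spread between libraries. Without wild type 2, 22 loci were higher and 130 lower. The count was 53 without pad2-1 2 and 43 without pad2-1 3. The DESeq2 Wald test ended the call of AT1G47389 (adjusted p = 0.865), with a fitted log2 change of 8.74 against 9.10 in edgeR, and 21 nt reads alone gave 3 calls.

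In vtc2-1 small RNA over AT1G12615, a protein-coding gene (chromosome 1, 4294055 to 4294540), was at least 120-fold higher than in wild type, over AT2G05675 at least 24.5-fold and over AT5G16410 at least 21.7-fold. AT4G05605 had 140 reads against 2, a ratio of 147 (39.9 to 1224), and XTH15 was at least 8.39-fold higher. Of the 34 lower loci 6 had 0 reads in vtc2-1, among them the noncoding RNA AT3G03945 (chromosome 3, 6988650 to 6988967) at least 174-fold lower, AT2G27520 at least 51.2-fold, AT3G56275 at least 20.7-fold, AT3G50300 at least 20.0-fold and AT3G49970 at least 14.1-fold. With edgeR 21 loci rose and 34 fell, and the named ones had adjusted p values from 5.17e-08 to 0.0290. Of the lower loci 85.3% were dominated by 24 nt reads (adjusted p = 6.20e-05, Fisher's exact test), as were 71.4% of the higher loci (0.0902). The count was 112 without wild type 3 and 30 without vtc2-1 1, and 27 with only the 2 genotypes compared, which ended the call of AT2G05675. The call of XTH15, at 18.9 CPM in vtc2-1 1 and 2.15 CPM in vtc2-1 2, ended without wild type 1 (adjusted p = 0.0992) or wild type 2 (0.0785). It also ended with the ligation-tag score, with weighted matches and with 24 nt reads alone, while DESeq2 gave AT5G16410 no adjusted p. The call of AT5G16410 ended with the ligation-tag score (0.220), where the fitted log2 change went from 7.26 ± 1.13 to 6.22 ± 2.22 (SE), and that of XTH15 from 5.88 ± 1.22 to 7.68 ± 2.15.

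In nahG small RNA over AT1G12615 was at least 136-fold higher than in wild type, over AT5G46295 at least 80.4-fold, over AT2G05675 at least 26.8-fold, over XTH15 at least 22.6-fold and over the MADS-box gene AGL48 at least 16.3-fold. AT1G14780 was at least 127-fold lower, AT2G37130 at least 49.7-fold and AT3G19880 at least 30.7-fold. AT3G57480 (chromosome 3, 21277270 to 21279404) fell by 9.08 ± 1.20 on the log2 scale (2064 ± 209 to 4.09 ± 2.49 CPM), and AT5G43755 had 2 reads against 1168 (ratio 370, interval 102 to 3063). Over the alternatives the log2 change of AT3G57480 in nahG ran from −9.46 to −5.36, past the threshold in 15 of 15. The small RNA of AT3G57480 varied within pad2-1, with 2.21, 808 and 225 CPM in its 3 libraries. In nahG 69.2% of the higher loci had at least 95% of reads on 1 strand, against 26.97% of tested loci (adjusted p = 5.57e-39, Fisher's exact test), and 6.38% of the lower loci (4.28e-18). These p values count loci of the same libraries as independent and do not measure the spread between libraries. Only 13.8% of the higher loci were dominated by 24 nt reads, against 81.9% of the lower loci and 49.3% of tested loci, and 11.2% of the higher loci were snRNA or snoRNA genes against 2.42% of tested loci (adjusted p = 7.94e-10). The share of all snRNA and snoRNA reads was 0.821% ± 0.307 in nahG and 0.769% ± 0.459 in wild type, with 0 of 3 nahG libraries outside the wild-type range. The share of rRNA fragments was also higher in these libraries, as given above.

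With edgeR 224 loci rose and 282 fell in nahG, and the named ones had adjusted p values from 1.88e-11 to 0.00163 with 3 of 3 libraries outside the wild-type range. The count was 236 without wild type 1, 285 without wild type 2, 968 without wild type 3, 168 without nahG 2 and 289 without nahG 3; 150 loci held in each of these fits and without nahG 1. Higher and lower loci numbered 150 and 561 without a low-count filter, and 168 and 362 by the DESeq2 Wald test. With the ligation-tag score 131 of the 506 calls remained, and over the 375 that ended, all with the same sign, the median size of the log2 change went from 1.03 to 0.88 and the median SE from 0.25 to 0.35. Among these were AT5G46295 (9.04 ± 0.89 to 5.99 ± 1.76, adjusted p = 0.0831) and AGL48 (6.82 ± 1.13 to 6.01 ± 2.76, 0.313). The DESeq2 Wald test gave no adjusted p for AT5G46295, AT2G05675, XTH15, AGL48 and AT2G37130.

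**Figure D3:**
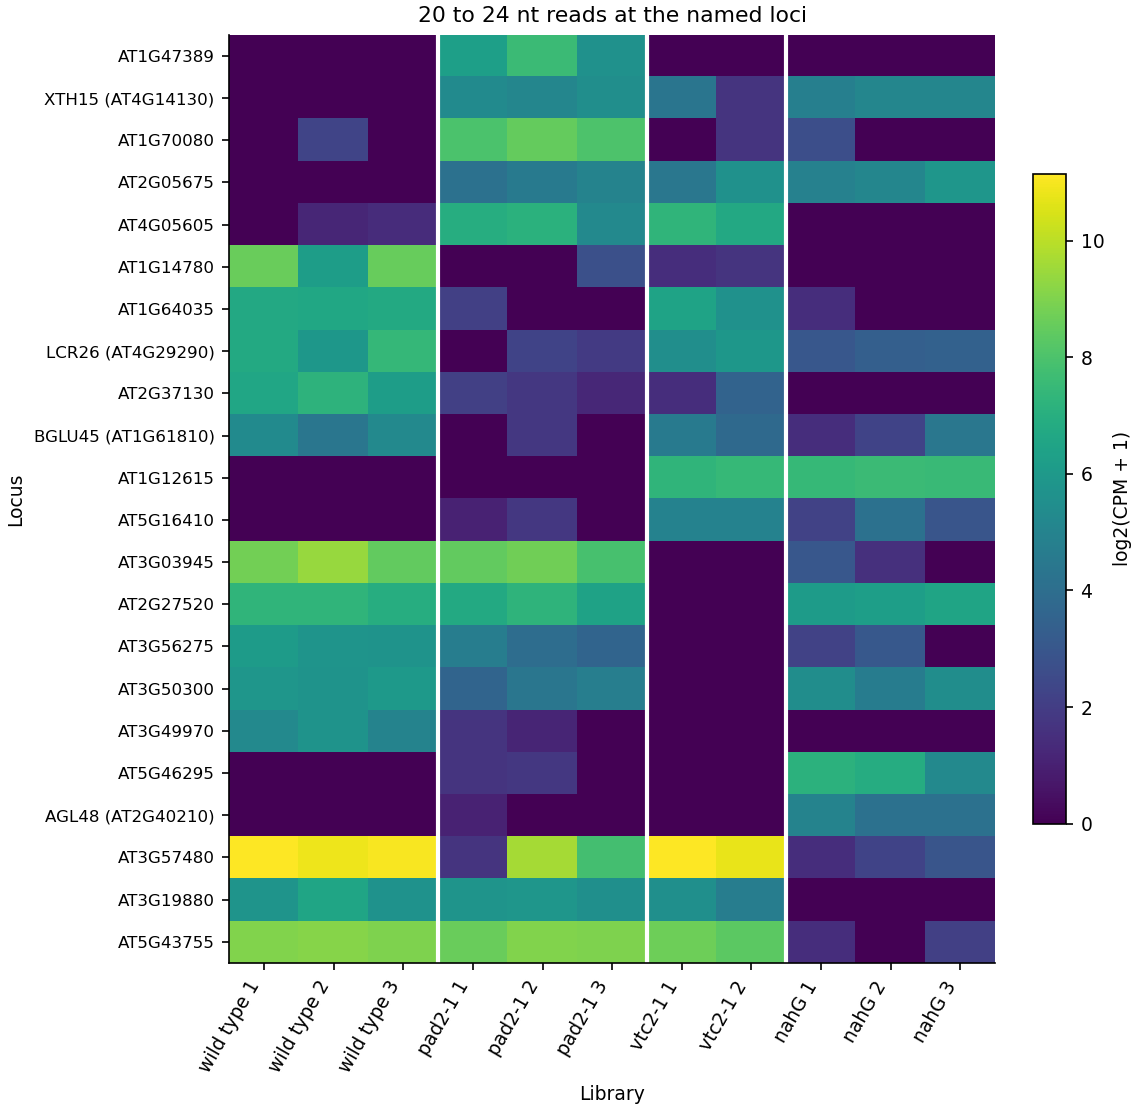
Reads of 20 to 24 nt at the named loci in each library, as log2 of CPM with a pseudocount of 1, with libraries as columns and white lines between genotypes. AT1G12615 is dark, at 0 reads, in the 3 wild-type libraries and bright in vtc2-1 and nahG, and AT3G57480 has 2064 CPM in wild type and 4.09 in nahG.

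**Figure D4:**
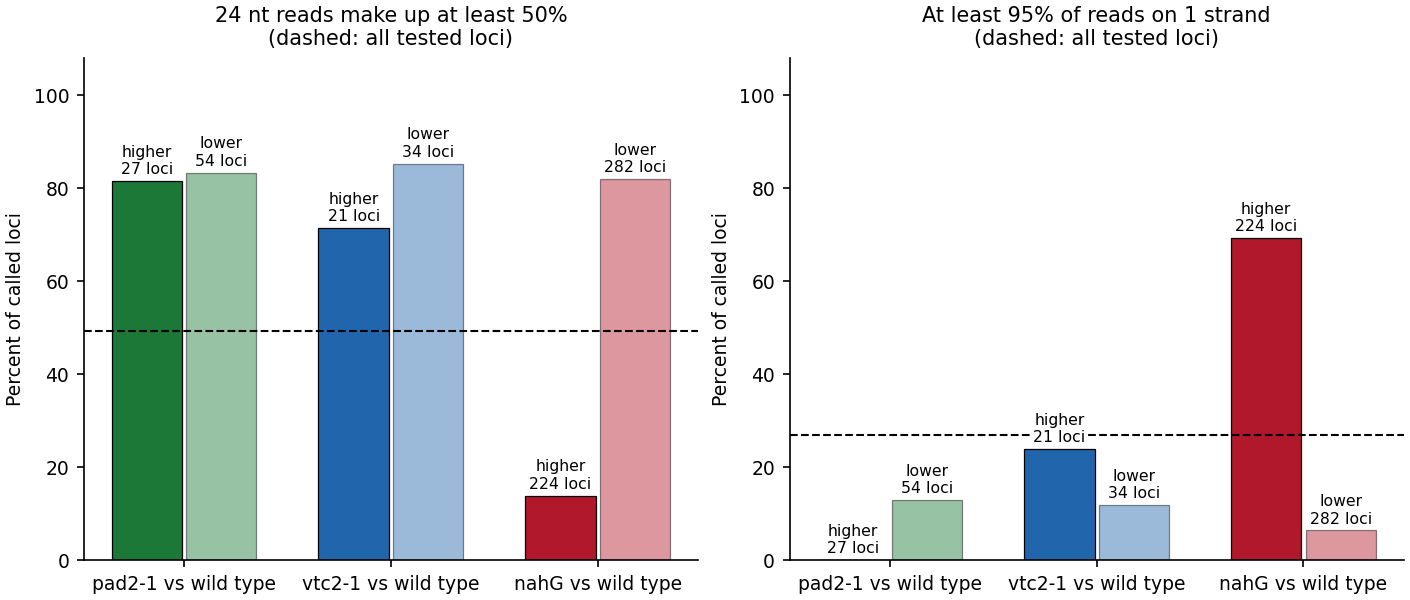
Percent of called loci at which 24 nt reads make up at least 50% (left) and at which at least 95% of reads lie on 1 strand (right), for loci higher or lower in each mutant, with a dashed line at the percent of all tested loci. Of the loci higher in nahG 13.8% are dominated by 24 nt reads and 69.2% have reads on 1 strand, against 49.3% and 26.97% of tested loci.

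The trans-acting siRNA genes and the mutated genes were read in every comparison. In nahG the log2 change of TAS1B was −0.60 ± 0.18 (SE; adjusted p = 0.0530), that of TAS2 −0.49 ± 0.19, that of TAS1A −0.35 ± 0.25, that of TAS3, whose siRNAs target auxin response factors, −0.32 ± 0.16, that of TAS1C −0.23 ± 0.18 and that of TAS4 0.42 ± 0.43. In pad2-1 they were 0.61 ± 0.25 for TAS1A, 0.47 ± 0.18 for TAS1B, 0.38 ± 0.19 for TAS2, 0.35 ± 0.16 for TAS3, 0.03 ± 0.18 for TAS1C and −0.30 ± 0.43 for TAS4. In vtc2-1 they were −0.53 ± 0.20 for TAS1B, −0.40 ± 0.18 for TAS3, −0.24 ± 0.22 for TAS2, −0.11 ± 0.28 for TAS1A, 0.07 ± 0.20 for TAS1C and 0.25 ± 0.48 for TAS4. None passed, though TAS1A (−0.81), TAS1B (−0.75) and TAS2 (−0.77) passed in nahG without nahG 1, TAS1B (−0.78) without wild type 3, and TAS1B (−0.67), TAS2 (−0.55) and TAS3 (−0.38) in DESeq2. Without a low-count filter TAS1A passed in pad2-1 (0.61), and TAS1A (−0.55), TAS1B (−0.81) and TAS2 (−0.68) in nahG, where TAS1B also passed with 21 nt reads alone and TAS1C with 24 nt reads alone. The log2 change of small RNA over GSH1 was −0.50 ± 0.28 in pad2-1, −0.19 ± 0.32 in vtc2-1 and 0.57 ± 0.28 in nahG, and passed in nahG without wild type 3 (0.97, adjusted p = 0.0131). That over VTC2 was −0.38 ± 0.28, 0.16 ± 0.32 and −0.11 ± 0.29. Small RNA reads do not read the mutations themselves.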

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

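The groups of 2 or 3 libraries were too small for a search for outlying libraries, and the read classes below were defined after unmatched reads were seen. Wild type 3 still differed from every other library in values picked afterwards and not tested. Its chloroplast share was 18.7%, against 6.55 to 12.3%. Distinct pairs of ligation tags and insert made up 50.8% of its 18 to 31 nt reads, against 63.7 to 75.8%. Some reads matched no position of the genome, and their share was above the highest wild-type library in several libraries. Adapter-derived reads made up at most 2.30% of the 18 to 31 nt reads in wild type (wild type 2, 95% Wilson interval 2.295 to 2.310%). They made up 7.62% in pad2-1 3, 2.35% (2.347 to 2.363%) in vtc2-1 1, 4.10% in vtc2-1 2, 10.7% in nahG 1, 7.98% in nahG 2 and 24.5% (24.49 to 24.55%) in nahG 3. These reads enter none of the miRNA or locus counts.

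Unmatched reads that ended in CCA, the bases added to the 3′ end of mature tRNAs, made up at most 1.94% in wild type. They made up 2.66% in pad2-1 1, 2.18% in vtc2-1 1 and 2.33% in vtc2-1 2.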

How the results depend on the processing

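The fits with a ligation-tag score, with matched or distinct ligation tags and with genome-matched length shares, and the rule for a reversed share, were chosen after the data were seen. The fewest mature miRNA reads were in nahG 3 (499984), and with 3 against 3 libraries, simulated changes of log2 1 were recovered at 35 and 50% of miRNAs and 32 and 30% of loci in pad2-1 and nahG. Of 2014 values of named miRNAs and loci under the alternatives, 98 changed sign and 5 reversed, that is with a call in either fit or with both changes larger than their SE. For shares, 42 of 409 changed sign and 3 reversed; counting a reversal only where both differences exceed 1 SE was settled after those changes were seen. The cause was not tested for the changes below.

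Without a low-count filter 9 miRNAs were called in pad2-1, 12 in vtc2-1 and 5 between vtc2-1 and nahG, and 211 loci in pad2-1 and 119 in vtc2-1. With DESeq2 size factors 2 miRNAs were called in vtc2-1, and the DESeq2 Wald test called 41 in nahG. With the library size of all genome-matched reads 0 were called in vtc2-1 and 55 in nahG, and in nahG miR168a-5p/b-5p was at −0.63, miR398b-3p/c-3p at −0.71 and miR408-3p at −0.44. Reads per MIR gene gave 0 in vtc2-1, and isomiRs 43 in nahG. With only the 2 genotypes compared 0 miRNAs and 27 loci were called in vtc2-1 and 14 miRNAs in nahG. With the ligation-tag score 0 miRNAs and 105 loci were called in vtc2-1, 5 miRNAs and 194 loci in nahG, and miR167a-5p/b in vtc2-1 was at 0.29. With distinct ligation tags counted 0 miRNAs were called in vtc2-1 and 3 lists passed, and the median miRNA moved by −0.19 in vtc2-1 and −0.22 in nahG. Reads of 21 nt alone gave 3 loci in pad2-1, 1 in vtc2-1 and 96 in nahG, and 24 nt reads alone 266 in nahG. The difference of the 23 nt share in nahG was −1.74 points over distinct sequences, against 1.03. Over reads with 1 match the difference of the MIR share was 0.298 points in vtc2-1, against −3.60. That of the protein-coding share over reads with 1 match was 1.65 points in vtc2-1 and 1.503 in nahG, against −0.443 and −0.700. In vtc2-1 the main edgeR fit made 4 miRNA calls, with 28 miRNAs at an unadjusted p under 0.05, and the DESeq2 Wald test also made 4. Unadjusted counts of the fits with 0 calls are not given here.

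The replicate numbers did not pair the libraries (4 of 15 correlations over 0.1). With them as a replicate block 6 miRNAs were called in vtc2-1 and 34 in nahG, and 0 in vtc2-1 when its libraries were numbered 2 and 3, as in their titles.

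Leaving out each library in turn gave these ranges, where the omission of vtc2-1 1 or vtc2-1 2 leaves 1 vtc2-1 library. For miRNAs they were 0 (without wild type 1, wild type 2, vtc2-1 1 or vtc2-1 2) to 28 (without wild type 3) in vtc2-1 and 8 (without nahG 2) to 64 (without wild type 3) in nahG, with 11, 13 and 12 without wild type 1, wild type 2 and nahG 3. Between mutants they were 4 (without vtc2-1 1) to 31 (without pad2-1 1) for pad2-1 and vtc2-1, 37 (without nahG 2) to 62 (without nahG 1) for pad2-1 and nahG, and 2 (without vtc2-1 1) to 5 (without vtc2-1 2) for vtc2-1 and nahG. For loci they were 43 (without pad2-1 3) to 152 (without wild type 2) in pad2-1, 30 (without vtc2-1 1) to 112 (without wild type 3) in vtc2-1 and 168 (without nahG 2) to 968 (without wild type 3) in nahG. The list count was 0 to 3, with 3 without wild type 3. In vtc2-1 miR396b-5p ranged from −0.31 (without vtc2-1 1) to 0.69 (without wild type 3). In nahG miR391-3p, miR391-5p, miR161.1 and miR395a/d/e passed in 16 of 16 alternatives.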

Other observations

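All tests below were chosen after the result was seen, except the comparison of wild type 3 with the other wild-type libraries at the loci higher in nahG.

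Loci called in all 3 mutants were counted, and those named here were chosen after their values were seen. There were 6 higher, where independent lists would share 0.00164, and 12 lower, where they would share 0.00668. The higher ones were XTH15, the circadian RNA-binding protein gene GRP7, AT5G26700, the pseudogene AT2G11930 and the overlapping noncoding RNAs AT2G05665 and AT2G05675. AT2G05675 lies within AT2G05665 and was given the reads of the overlap, so these are parts of 1 region without shared reads. Among the lower ones were the MADS-box gene AGL12, AT1G14780, AT2G37130, AT3G49970 and AT5G35100. The 3 comparisons use the same 3 wild-type libraries, which are too few to divide between them. In simulated counts with the same shared wild type and no difference between genotypes, the mean number of loci called in the same direction in 2 mutants was at most 0.05 over 20 draws, against 8 higher and 14 lower for pad2-1 with vtc2-1, 10 and 27 for pad2-1 with nahG, and 14 and 22 for vtc2-1 with nahG. Counts without a genotype difference give few calls in any mutant. They therefore cannot show how much of these overlaps comes from the shared wild-type libraries. The values for independent lists do not allow for the shared libraries either. Over all tested loci the correlation of the log2 changes was 0.326 for pad2-1 with vtc2-1 (simulated 0.416), 0.265 for pad2-1 with nahG (0.465) and 0.447 for vtc2-1 with nahG (0.375), and their covariance 0.125 (0.0875), 0.127 (0.0873) and 0.240 (0.0878). For miRNAs, 3 were higher in both vtc2-1 and nahG, where independent lists would share 0.311, namely miR159b-5p, miR162a-3p/b-3p and miR167d, and their libraries share a ligation-tag composition.

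Small RNA of the loci called in nahG was also compared with vtc2-1, whose libraries share the ligation-tag composition of nahG. Of 224 loci higher in nahG than in wild type, 21 were higher in nahG than in vtc2-1, of the 33 called there. Of 282 lower loci, 71 were also lower than in vtc2-1, of the 89 called there. Both comparisons use the same nahG libraries, so these overlaps were not tested. The tested loci neighbouring MIR391 were not called in nahG: ALP (log2 change 0.02), AT5G60390 (0.58, adjusted p = 0.193), SIZ1 (−0.44), the auxin response factor gene ARF4 (−0.30) and AT5G60560 (−0.57, 0.312).

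In nahG 13 miRNAs were higher and 13 lower than in wild type. The nahG and vtc2-1 libraries share 1 ligation-tag composition, and miR391-3p, miR391-5p and miR393b-3p were lower in nahG than in vtc2-1. A batch marked by the tags would not give that difference. These 3 were picked because they were the only calls there, so their being called is no separate test of batch. The difference was smallest for miR393b-3p, at log2 1.69, and 1.37 without vtc2-1 1, which leaves 1 vtc2-1 library. For the others batch and genotype cannot be told apart, because no composition holds both genotypes: 5 calls remained with the ligation-tag score as covariate, 11 of the 13 higher and 13 of the 13 lower miRNAs kept their sign in nahG against vtc2-1 (medians 0.54 and −1.09), and 12 and 11 had it in vtc2-1 against wild type (1.09 and −0.61), in comparisons that share libraries with the calls. A bias of adapter ligation, which acts on each sequence by itself, may contribute. The log2 changes of 2 mature sequences were paired at each of 10 precursors with a called sequence. Pearson r was 0.69 (permutation p = 0.0344) and Spearman rho 0.248 (permutation p = 0.490). This Pearson r met the rule set first against ligation bias. Without the 2 farthest precursors r was 0.132 (permutation p = 0.768). Leaving them out was a requirement added after the value was seen, because r rested on MIR391. Over all 42 precursors, which are not independent replicates, r was 0.59 (permutation p = 3.3e-04). Without the 2 farthest it was 0.356 (permutation p = 0.0229). Over the same 42 precursors r was 0.374 (permutation p = 0.0137) in pad2-1, with 0 miRNAs called, and 0.108 (permutation p = 0.497) in vtc2-1. An r above 0 would be found without such a bias, but it also appeared in pad2-1 without a call, so it does not decide. Not every pair was the 2 arms of 1 precursor, so these r values compare arms only in part. Of the 10 pairs, that of miR161.2 with miR161.1 is not labelled as opposite arms. Of the 42, that of miR447a.2-3p with miR447a-3p/b has 3p labels only. Some paired sequences, such as miR160a-5p/b/c-5p, stand for several genes. The called pairs as a set do not decide, so ligation bias stays open. Low salicylate also stays open. It was not separated from other features of the nahG line for any miRNA. For miR391-3p, miR391-5p and miR393b-3p, only a batch marked by the ligation tags would not give the difference from vtc2-1. Other batches are not in the labels and were not tested. For the other miRNAs the line itself was not separated from batch.

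In pad2-1 81 loci differed from wild type, 22 of the 27 higher and 45 of the 54 lower ones with at least 50% 24 nt reads. A batch marked by the ligation tags is argued against, since 55 of the 81 calls remained with the 2 wild-type and 2 pad2-1 libraries of 1 ligation-tag composition. These libraries had also made the calls, and leaving out single libraries kept 43 to 67 of them. The vtc2-1 and nahG libraries stayed in that fit. Other batches are not in the labels and were not tested. Deletion of the loci is argued against as a general cause, since 13.6% of them had 3 or fewer reads in the lower genotype. Linked segments of another genetic background could place the loci near each other: the one-sided permutation p of the median distance to the nearest called locus was 0.0102 for every locus, 0.0104 with loci within 10 kb counted once, and 0.138 when random sets also matched the number of 24 nt loci, the version used because 24 nt loci lie in clusters. That explanation and low glutathione, which was not tested apart from it, stay open.

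In nahG 224 loci had more small RNA than in wild type. Fragments of longer RNAs are a candidate explanation, since 69.2% of these loci had reads on 1 strand and few were dominated by 24 nt reads. A library batch would place wild type 3, nearest to nahG in ligation tags, above the other wild-type libraries. Its median log2 ratio to them was 0.0207 (quartiles −0.31 to 0.39, above 0 in 52.2% of the loci), against 0.00350 and 50.3% over all tested loci. Loci where wild type 3 lay near nahG were less likely to be called, which draws this ratio down. Of the 224 loci 213 kept their sign in nahG against vtc2-1 of the same composition (median 0.64, against 1.22 to wild type), and 200 had it in vtc2-1 against wild type (0.56), in comparisons that share libraries with the calls. The first value lay between the bounds set beforehand for and against a batch, and no composition holds both nahG and wild type, so batch and genotype cannot be told apart for these loci.

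The libraries of 3 against 3 make 10 splits, too few for a share under 0.05. As many calls as the real split came from 10 of 10 splits for miRNAs in pad2-1 (0 calls) and from 1 of 10 for miRNAs in nahG (26), miRNAs between pad2-1 and nahG (68), loci in pad2-1 (81) and loci in nahG (506), and the highest of the other splits was 0 in each.

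Single libraries stood apart for some miRNAs, chosen after their values were seen. The level of miR843 was 2023 CPM in pad2-1 2 and 44.9 to 142 CPM in the others, and that of miR164c-3p was 175 CPM in wild type 3 and 5.44 to 58.9 CPM in the others. Reads of miR1886.2 were 0 in nahG 3, against 9.20 to 35.6 CPM in the others. The pollen miRNA miR845a had 0 to 9 reads per library.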
